A study of Homo sapiens with 6 samples.

How the data were processed

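The series holds 6 RNA libraries from blood mononuclear cells of patients with systemic sclerosis. Per the labels' protocols, frozen cells were thawed and sorted into CD4 CTL and naive CD4 T cells, RNA was purified on RNeasy Plus Micro columns, and libraries followed the mcSCRB-seq protocol adapted to bulk RNA, a method that primes cDNA from the poly(A) end. Groups and replicate numbers were taken from the sample titles, 3 libraries per group. The titles describe the CD4 CTL as CD57-high as well, which the sort given in the labels' protocols does not mention.

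Each deposited table held 1 library and 31056 genes. The deposited values were a per-gene signal in normalised counts: every value (100% of them, within a tolerance of 0.001 of a whole number) was a whole number of reads times the value of 1 read, which was constant within a library and lay between 0.496 and 1.63. Reads were recovered by this division. Per the submitters' processing notes, STAR 2.5.4a, SAMtools 1.9, R 3.5.1, DESeq and DESeq2 1.22.1 were used with GRCh38.p12, with no role given. The gene annotation, the counting tool, its use of strand and the handling of molecular identifiers are not given in the sources used here, so "reads" here may be reads or identifiers, and intervals cover counting error only. All 31056 identifiers matched GENCODE 29, from which symbols, gene types and GRCh38 coordinates were taken. XIST, TSIX and Y-linked genes (354 rows) were removed before every step, which left 30702 rows, 3397 of them 0 in all libraries. The removal and the deposited scaling affect shares and fold changes: shares are of the reads in the remaining rows.

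The test planned for counts (edgeR) was replaced by limma on log2(normalised count + 1) because the deposited values were not raw counts. The pseudocount of 1 shrinks fold changes of low genes. The fit used limma 3.58.1 with an intensity trend in R 4.3.3, without a term for the patient, on genes kept by the filterByExpr rule of edgeR 4.0.16 (a count near 10 in 3 libraries and 15 in all), and Benjamini-Hochberg adjustment with a threshold of 0.05. The edgeR quasi-likelihood test on recovered reads and DESeq2 1.42.0 served as alternatives. Lists were tested with camera at a preset correlation of 0.01, two-sided, for lists with at least 5 tested members, with adjustment over the 12 lists, and again with an estimated correlation and with fry. The 33 lists held 582 genes, of which 211 were tested and 20 were not analysed here for want of a row. The genes of the list describing the sort were not tested as a list. Adjustment over a list alone covered only the members tested in that fit. Shares of reads were compared with exact permutation tests over 10 splits.

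The lists, groups, named-gene rule and most alternatives were fixed before the data were examined. The rule named up to 12 genes per direction past the threshold that moved alike in 3 of 3 patients with a mean CPM of at least 20, and up to 4 members of each list with the smallest p, besides tested sort genes. Left out were HLA class I, HLA-DR B, DQ and DP genes, KIR genes, T cell receptor and immunoglobulin segments and genes with common deletions, and, among genes past the threshold, pseudogenes and unnamed loci. The rule gave 74 genes, of which the text names 54: the first 4 of each list past the threshold, the first 2 of other lists, those that passed adjusted over their list alone among the 4, and the sort genes. Other genes are named with a statement that they were chosen after their values were seen.

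Libraries with the same replicate number come from the same patient, whose number the labels give, so the numbers pair the samples. The correlation of their deviations from the group means was 0.182, 0.161 and -0.0365 for pairs 1 to 3, and with the replicate block 0 genes passed in limma and edgeR and 2 in DESeq2. No library was a copy of another: chi-square per degree of freedom was at least 4.03 between libraries of a group and at least 3.29 between groups, and correlations of log values were 0.726 to 0.823 within groups and 0.725 to 0.824 between them.

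The fit was tested on simulated counts with the real means, dispersions and library sizes, 10 draws with 200 changed genes and on average 3150 tested genes. It recovered 0.547% of genes changed by log2 1, 13.3% of those changed by 2 and 48.6% of those changed by 3, with 1.3 false calls among 32.1 calls per draw. A shift of log2 1 in the 9 tested cytotoxic genes was called in 9 of 10 draws, and 0 of 131 list tests without a change were called. Simulated genes were independent, which real genes are not. The same filter kept 2324 genes of the real data, so the simulated counts differed from the real ones, and these rates may not hold for the real data.

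Alternatives were other scalings (median of ratios, upper quartile, library totals, TMM), other filters, pseudocounts of 0.5 and 5, limma-voom, the replicate block, thinning to 169760 reads, removal of mitochondrial and ribosomal protein genes before scaling, a test against a fold change of 2, and leaving out each library and each patient. Figures were drawn with matplotlib 3.10.9, and sequences were searched with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.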

Results

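Gene expression was measured in 2 populations of blood CD4+ T cells from patients with systemic sclerosis, an autoimmune disease with vascular injury and fibrosis of skin and organs. CD4 CTL are CD4+ T cells that carry the granule proteins usually found in killer lymphocytes; here they were sorted as CCR7-negative, CD45RA-negative, SLAMF7-positive cells with low CD28. Naive CD4 T cells, which have not yet met antigen, were sorted as CCR7-positive, CD45RA-positive cells from the same patients. There were 3 libraries per group, and replicate numbers mark the patient. The libraries were small: the recovered read totals were 169760, 359540 and 214520 in naive CD4 replicates 1 to 3 and 808180, 338850 and 195950 in CD4 CTL replicates 1 to 3. Between 15621 and 23406 genes had at least 1 read in a library, and 2324 genes had enough reads to be tested.

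CD4 CTL were compared with naive CD4 T cells, the only other population in the series. The gates also differed in CCR7 and CD45RA, and no other antigen-experienced CD4 population was included. Differences may therefore belong to the cytotoxic cells or to antigen-experienced cells in general, which cannot be told apart here. Transcripts of cytotoxic granule genes such as NKG7 and GZMA, of cytoskeleton and motility genes and of the mitochondrial genome were higher as groups in CD4 CTL, while a single gene, RAP1GAP, passed the test taken gene by gene. The 3 list calls were lost when the correlation between genes was estimated (adjusted p = 0.305, 0.305 and 0.864), and NKG7 and GZMA did not pass over all genes (adjusted p = 0.408 and 0.41). RAP1GAP (ENSG00000076864, chromosome 1, 21596215 to 21669363, GRCh38) encodes a GTPase-activating protein for Rap1, a small G protein that controls integrin adhesion in T cells. Its normalised read count was 47.0 ± 17.9 (SD, n = 3) in naive CD4 and 2.82 ± 1.17 (SD, n = 3) in CD4 CTL, from 125 and 12 reads, and it was lower in CD4 CTL in 3 of 3 patients. Its log2 fold change was -3.64 ± 0.52 (SE; limma, Benjamini-Hochberg adjusted p = 0.0266), on the scale of log2(normalised count + 1). The call was lost when the patient was fitted as a replicate block (adjusted p = 0.223 with limma and 0.273 with edgeR, where 0 genes passed; DESeq2 kept it, 0.0148). It was also lost without any 1 of naive CD4 replicates 1, 2 or 3 (adjusted p = 0.261, 0.274 and 0.619), without CD4 CTL replicate 1 (0.0706), without the replicate 1 pair (0.395) or the replicate 3 pair (0.297), with limma-voom (0.343) and when all genes with a mean normalised count of at least 5 were tested (0.0725). Its log2 fold change stayed between -3.95 and -3.07 when a library or patient was left out.

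In the main fit no gene passed the threshold of 0.05 in the direction of higher expression in CD4 CTL. GPT2, chosen after its values were seen, did so in limma with no filter (log2 fold change 3.78, adjusted p = 0.00875) and in DESeq2 with the replicate block (4.07, adjusted p = 0.0435). Without adjustment 209 of the 2324 genes lay under 0.05, of which 182 were higher and 27 lower in CD4 CTL, where chance would give 116.2. The edgeR quasi-likelihood test on the recovered reads called 1 gene, RAP1GAP (adjusted p = 0.0406), and DESeq2 called 2, RAP1GAP among them (adjusted p = 0.000534). The 3 values of one group lay entirely above or below those of the other in 406 genes (17.5%), where chance gives 10%. Both chance values assume no shift common to all genes, and the shift given next may add to both excesses. The deposited scaling set the median log2 fold change of all tested genes at 0.32, and other scalings moved it to between 0.08 (library totals) and 0.30 (upper quartile). On this scale 70.5% of all tested genes had a positive fold change. Fold changes of single genes include this shift, as do counts of members that were positive or higher in 3 of 3 patients. The list tests compared each list with all other tested genes.

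Cytotoxic granule genes were the list with the highest median log2 fold change of the 12 tested. Of its 19 members 9 could be tested, and their median log2 fold change was 1.47, which is 1.15 above the median of all genes (camera with a preset correlation of 0.01, adjusted p = 7.6e-05). With an estimated correlation the call was lost (adjusted p = 0.305). None of the 9 passed adjusted over all genes, and 7 were higher adjusted over the list alone. With no filter 6 of the 19 members passed over the list alone. GZMB and PRF1, chosen after their values were seen, were not among the 9. NKG7, a membrane protein of cytotoxic granules, had normalised counts of 7.88 ± 5.29 in naive CD4 and 35.3 ± 13.4 in CD4 CTL (SD, n = 3), a log2 fold change of 2.17 ± 0.57 (SE). GZMA, the granule serine protease granzyme A, had 27.2 ± 24.4 and 88.1 ± 1.26, a log2 fold change of 2.12 ± 0.60. Leaving out a library or patient moved these 2 fold changes between 1.38 and 2.96 and between 1.32 and 2.84. CTSC, the protease that activates granzymes, had 18.9 ± 5.59 and 53.5 ± 8.47 (log2 fold change 1.47 ± 0.38), and CST7, an inhibitor of cysteine proteases found in cytotoxic cells, had 6.76 ± 3.62 and 24.2 ± 7.57 (1.77 ± 0.53). All 4 were higher in CD4 CTL in 3 of 3 patients, and 5 of the 9 tested members were. These counts include the shift of all genes given above.

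**Figure D1:**
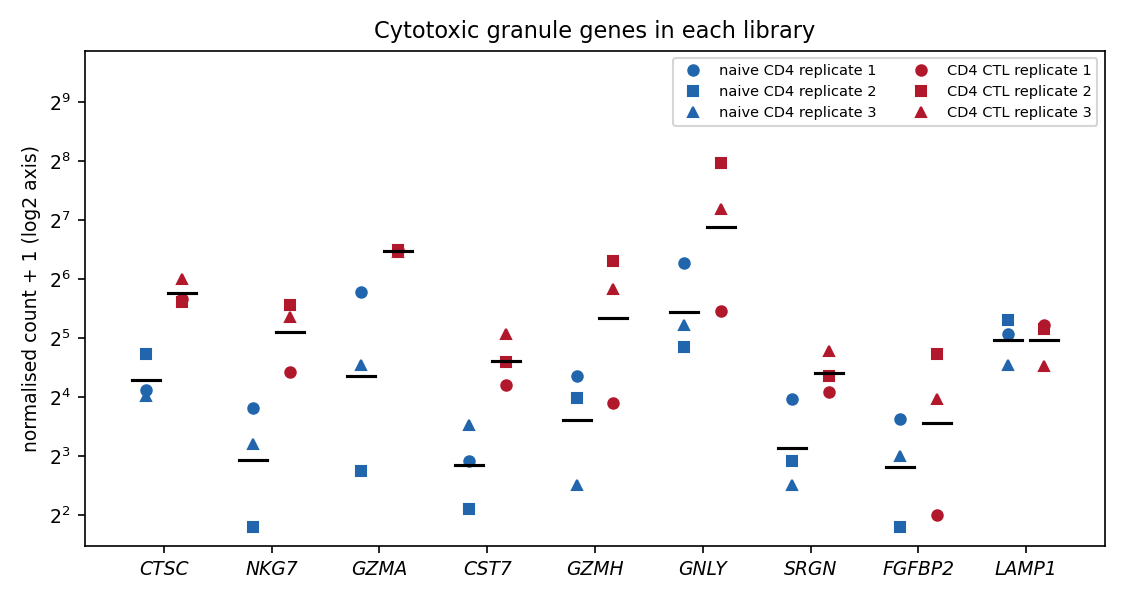
Normalised read count plus 1 (vertical, log2 axis) of the 9 tested cytotoxic granule genes in each of the 6 libraries, with naive CD4 in blue, CD4 CTL in red, symbol shapes for replicates 1 to 3 and black bars for the mean of the log2 values of 3 libraries. CTSC, NKG7, GZMA and CST7 were higher in CD4 CTL in 3 of 3 patients, while CD4 CTL replicate 1 lay inside the range of the naive libraries for 4 of the other genes.

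Cytoskeleton and motility genes were also higher as a list in CD4 CTL. Of 35 members 22 were tested, 19 had positive fold changes and 16 were higher in 3 of 3 patients. Among all tested genes 70.5% had positive fold changes. The median log2 fold change was 0.96, which is 0.63 above all genes (camera, adjusted p = 1.54e-05), and the call was lost with an estimated correlation (adjusted p = 0.305). No member passed adjusted over all genes or adjusted over the list alone. The log2 fold changes with SE were 1.52 ± 0.40 for ANXA1, a membrane-binding annexin, 1.13 ± 0.38 for S100A6, a calcium-binding protein, 1.40 ± 0.48 for LCP1, an actin-bundling protein of leukocytes, and 0.92 ± 0.31 for TMSB4X, which binds actin monomers. TMSB4X has processed pseudogenes in the genome, and how the authors' counting divided such reads is not given in the sources used here.

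Mitochondrially encoded transcripts were the remaining list past the threshold. Of 13 members 11 had a row and were tested, and MT-ND4 and MT-CO3 had no row. All 11 tested members had positive fold changes, as had 70.5% of all tested genes, and were higher in CD4 CTL in 3 of 3 patients. Their median log2 fold change was 0.76, which is 0.44 above all genes (camera, adjusted p = 0.000955). The call was lost with an estimated correlation (adjusted p = 0.864), without naive CD4 replicate 2 (0.06) and without the replicate 3 pair (0.0509). No member passed adjusted over all genes or adjusted over the list alone. Log2 fold changes were 1.17 ± 0.48 for MT-ND6, 1.06 ± 0.44 for MT-CO2, 0.98 ± 0.38 for MT-ATP8 and 0.92 ± 0.39 for MT-ND5 (SE), which encode subunits of respiratory complexes and of ATP synthase. The nuclear genes of the respiratory chain, 31 of 43 tested, had a median of 0.45 and did not pass (camera, adjusted p = 0.309), with UQCRQ at 0.99 ± 0.42 and NDUFB7 at 0.83 ± 0.37. They passed with no filter (0.0043), with a mean count of at least 5 (0.0161), without naive CD4 replicate 1 (0.0248) and without the replicate 1 pair (0.00519). Cytosolic ribosomal protein genes, 71 of 76 tested, had a median of 0.29 (camera, adjusted p = 0.53), with RPL23A at 1.10 ± 0.41 and RPL24 at 0.85 ± 0.36. This list passed with no filter (0.00142), with a mean count of at least 5 (0.0077), without naive CD4 replicate 1 (0.0248) and without CD4 CTL replicate 2 (0.0449). The library totals scaling and edgeR turned the direction of the ribosomal protein list against all genes, with adjusted p = 0.858 and 0.877, and many of these genes share sequence with pseudogenes.

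**Figure D2:**
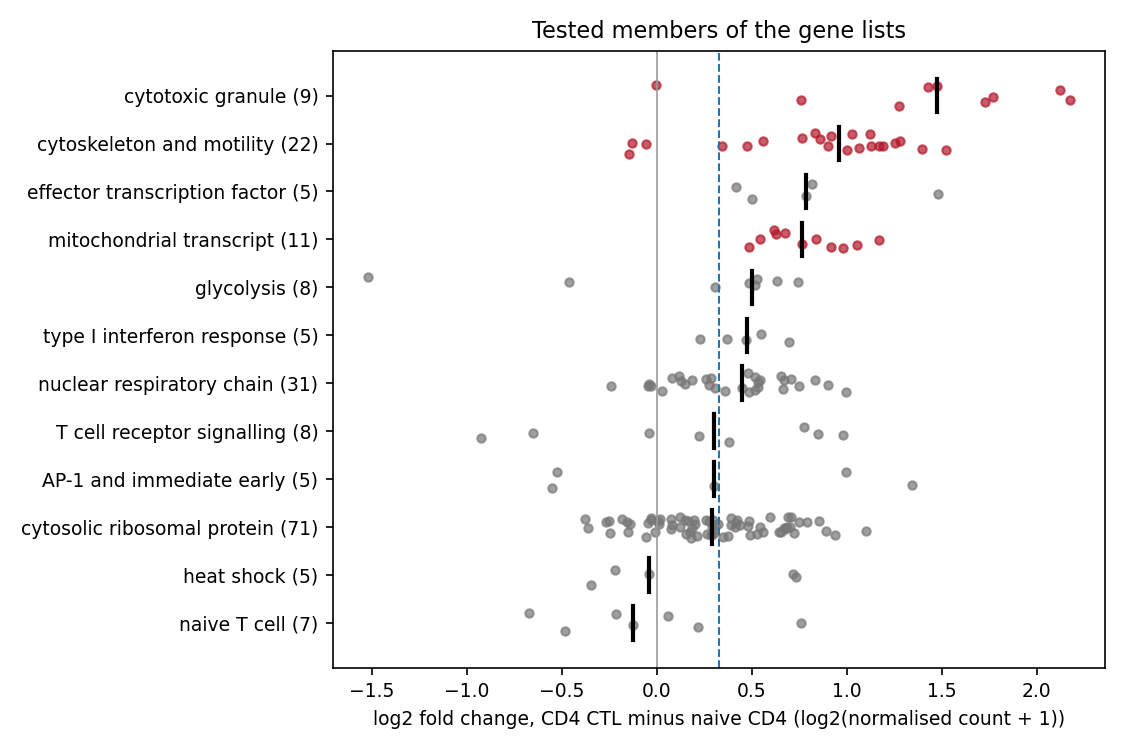
Log2 fold change of each tested member (points, horizontal axis, CD4 CTL minus naive CD4) of the 12 lists with a set test, with the number of tested members in parentheses, the list median as a black bar, 0 as a grey line and the median of all tested genes (0.32) as a dashed line. Lists past the threshold with a preset correlation are red, and their medians of 1.47, 0.96 and 0.76 lie to the right of the dashed line.

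Lists that describe the T cell state did not pass. The naive T cell list had a median log2 fold change of -0.12 over 7 tested members of 24, and its test against all genes pointed to lower expression in CD4 CTL (adjusted p = 0.232; it passed without CD4 CTL replicate 1, 0.0171, and without the replicate 1 pair, 0.0486). Its members IL7R, the receptor for interleukin 7, and BACH2, a transcriptional repressor of effector genes, had log2 fold changes of 0.76 ± 0.50 and -0.67 ± 0.61 (SE), and BACH2 turned to 0.26 without the replicate 3 pair. The effector transcription factor list had a median of 0.78 over 5 tested members (adjusted p = 0.108; 0.0127 without naive CD4 replicate 3). Its member ZEB2, a repressor expressed in terminal effector cells, reached 1.48 ± 0.47 and passed adjusted over the list alone, but not with no filter (limma, adjusted p = 0.0976). KLF6 had 0.78 ± 0.42. The type I interferon response list, 5 of 34 tested, had a median of 0.47 (adjusted p = 0.804), with SAMD9 at 0.70 ± 0.57 and MX2 at 0.47 ± 0.48. T cell receptor signalling (8 of 21 tested, median 0.30), AP-1 and immediate early genes (5 of 19, median 0.30) and glycolysis (8 of 20, median 0.50) had positive medians and means, yet their tests against the other genes pointed down (adjusted p = 0.804 for each). GRAP2 and NFATC2 had log2 fold changes of 0.85 ± 0.32 and 0.98 ± 0.64, DUSP1 and JUNB 1.34 ± 0.63 and 0.99 ± 0.57, and PFKP and ENO1 -1.52 ± 0.84 and 0.74 ± 0.45. When a library or patient was left out, PFKP ranged from -2.45 to -0.403, DUSP1 from 0.715 to 1.96 and JUNB from 0.405 to 1.51. The heat shock list, 5 of 14 tested, had a median of -0.04, a mean of 0.17 and a test pointing down (adjusted p = 0.804), with HSPA8 at 0.73 ± 0.43 and HSPH1 at 0.72 ± 0.45.

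The depth left 11 lists with 1 to 4 tested members, too few for a set test, and 9 lists with none. In the NK-type receptor list all 4 tested members passed adjusted over the list alone and none adjusted over all genes. These were CD2 and CD58, an adhesion receptor and its ligand, at 1.51 ± 0.41 and 1.19 ± 0.51, HCST, a signalling adaptor of NKG2D, at 0.95 ± 0.41, and KLRB1 at 1.19 ± 0.53, which was higher in 2 of 3 patients and ranged from 0.81 to 1.79 when a library or patient was left out. With no filter and adjustment over all 20 members with a row, CD2 passed (limma, adjusted p = 0.0171) and CD58, HCST and KLRB1 did not (0.134 each). Among 3 tested cytokine and chemokine genes, IL32 (1.23 ± 0.32) and CCL5 (1.29 ± 0.53) passed adjusted over the list alone, but not with no filter (limma, adjusted p = 0.0549 and 0.211). ITGB1, the integrin beta 1 chain, at 1.76 ± 0.41 in the homing list, passed over the list alone, also with no filter (0.0106). The other tested member of that list, ITGA4, had -0.24 ± 0.68. CD69, an early activation marker, had 1.36 ± 0.63 and HMGB2, a chromatin protein, had 1.24 ± 0.45; each was the only tested member of its list. CD69 ranged from 0.652 to 2.04 when a library or patient was left out. The apoptosis regulators CFLAR and BCL2 had 1.16 ± 0.47 and 0.27 ± 0.48, the quiescence factor FOXP1 had 0.62 ± 0.42, MAF had 0.50 ± 0.44 and RORA had 0.87 ± 0.50, and none of these passed over its list. RORA took 1.12% of reads on average, among the most counted genes without a known reason, and its fold change ranged from 0.184 to 1.46 when a library or patient was left out. The 2 tested members of the monocyte list, S100A8 and S100A9, had 0.25 ± 0.52 and -0.33 ± 0.68, and HBA2 of the erythrocyte list had -0.06 ± 0.53. The directions of ITGA4, BCL2, S100A8, S100A9 and HBA2 turned when a library or patient was left out.

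Genes that defined the sort were described and not tested as a list. CCR7, which was positive in the naive gate and negative in the CD4 CTL gate, had a normalised count of 16.7 ± 4.77 in naive CD4 and 5.10 ± 2.56 in CD4 CTL (SD, n = 3), a log2 fold change of -1.58 ± 0.63. PTPRC, whose isoform CD45RA entered both gates, had 1.37 ± 0.45, and the CD3 chains CD3G, CD3E and CD3D, common to both gates, had 0.97 ± 0.32, 0.67 ± 0.52 and 0.28 ± 0.32. CCR7, PTPRC and CD3G passed adjusted over the list alone. The fold change of CD3D turned negative with edgeR (-0.0173), limma-voom (-0.0913) and thinned libraries (-0.0258). The other gate genes, CD4, CD8A, CD8B, CD28 and SLAMF7, had too few reads to be tested. So had B3GAT1, which makes CD57, a marker that the titles name and the sort protocol does not, with normalised counts of 6.18 ± 5.89 in naive CD4 and 13.3 ± 15.2 in CD4 CTL (SD, n = 3), higher in 2 of 3 patients.

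Library composition was compared by an exact permutation test, in which 0.1 is the smallest p that 3 against 3 libraries allow, so no difference could reach 0.05. The 11 mitochondrially encoded protein-coding genes with a row, of 13 in the list, took 0.475% ± 0.140 of reads in naive CD4 and 0.711% ± 0.233 in CD4 CTL (SD, n = 3). Their share was higher in 3 of 3 patients (exact permutation test, two-sided, p = 0.3, adjusted 0.625 over 5 measures). Mitochondrial rRNA took 10.29% ± 1.71 and 13.03% ± 2.24 (exact permutation p = 0.2, outside the 5 measures) and was higher in 2 of 3 patients. Cytotoxic granule genes took 0.0771% ± 0.0206 and 0.168% ± 0.0700 (exact permutation p = 0.2, adjusted 0.625) and were higher in 2 of 3 patients. In CD4 CTL replicate 1 their share was 0.0902% (95% Wilson interval 0.0839 to 0.097), inside the range of the naive libraries, where replicate 1 had 0.101% (0.0867 to 0.117); these intervals cover counting error only. Cytosolic ribosomal protein genes took 5.53% ± 0.974 and 5.59% ± 0.764 (exact permutation p = 0.9, adjusted 0.9), and the 20 most counted genes 42.0% ± 4.80 and 44.9% ± 3.78 (exact permutation p = 0.5, adjusted 0.625). As shares of nuclear reads, ribosomal protein genes differed by 0.260 percentage points, against 0.0593 of all reads. The 20 most counted nuclear genes differed by 1.53, against 2.96 for the 20 most counted of all genes. After thinning to 169760 reads, 16950 ± 1164 and 16340 ± 804 genes were detected (exact permutation p = 0.5, adjusted 0.625). The permutation test leaves the pairing by patient aside. A paired sign-flip test, whose smallest p is 0.25, gave 0.25 for the mitochondrial transcript share. It gave 0.5 for the cytotoxic share, the mitochondrial rRNA share and genes detected after thinning, and 0.75 for the ribosomal protein and 20 most counted shares.

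**Figure D3:**
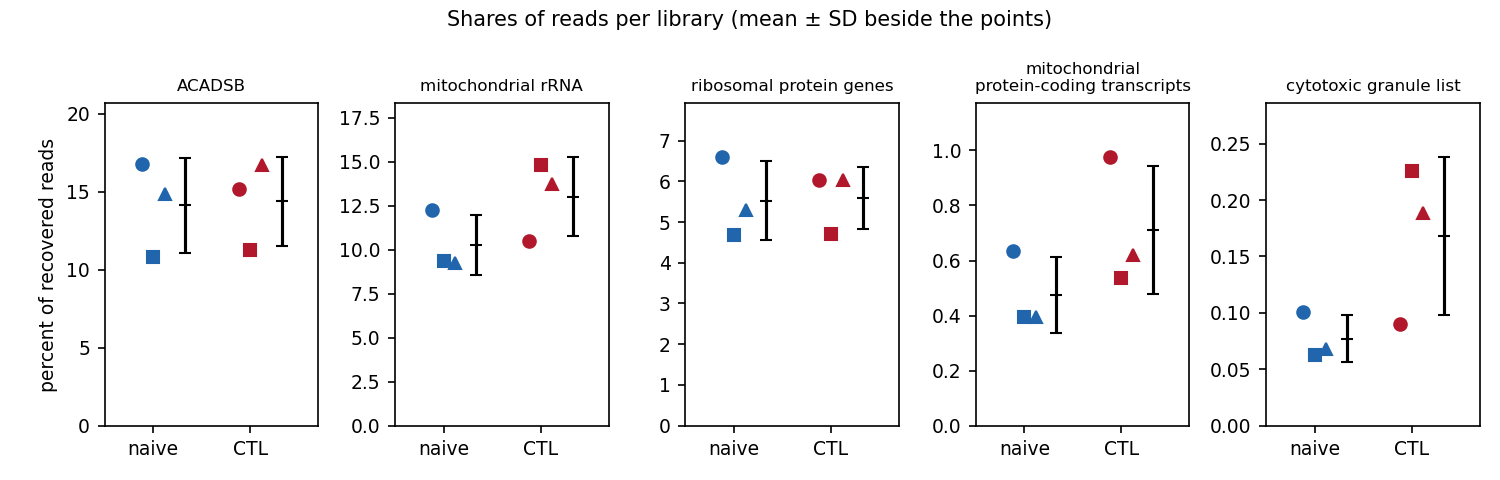
Percent of recovered reads (vertical axes, each from 0) taken by ACADSB, mitochondrial rRNA, cytosolic ribosomal protein genes, the 11 mitochondrial protein-coding transcripts with a row and the cytotoxic granule list in each library, with naive CD4 in blue, CD4 CTL in red and circle, square and triangle for replicates 1, 2 and 3. Black bars give the mean and SD of 3 libraries; ACADSB took 14.1% ± 3.06 in naive CD4 and 14.4% ± 2.84 in CD4 CTL.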

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

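TMM scaling, pseudocounts of 0.5 and 5, the edgeR test without the patient and the filter on a mean count of 5 were chosen after seeing the data. At this depth 2324 genes could be tested. Simulations with 3 libraries per group, in which 3150 genes on average were tested, recovered 0.547% of genes changed by log2 1 and 48.6% of those changed by 3. The 3 list calls held under every scaling, filter, pseudocount, limma-voom or edgeR fit, replicate block and thinning tried, with adjusted p from 3.68e-08 (cytoskeleton, mean count of 5) to 0.00514 (mitochondrial, thinned), and ended with an estimated correlation or fry. When a library or patient was left out, cytotoxic granule genes (2.26e-08 to 0.0348) and cytoskeleton genes (4.5e-06 to 0.00566) kept their calls. The cause of the changes below was not tested, except that filters change the genes tested and that fry compares a list with 0 and not with other genes.

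The count of genes changed (1) became 2 with no filter, DESeq2 and DESeq2 with the replicate block, and 0 with a mean count of at least 5, limma-voom, the replicate block, edgeR with the replicate block and a test against a fold change of 2. It ranged from 0 to 2 when a library or patient was left out. With DESeq2 the replicate block kept RAP1GAP (0.0148), gained GPT2 (4.07, 0.0435) and lost ZHX1 (0.000534 without the block), the last 2 chosen after their values were seen. The number of lists past the threshold (3) became 8 of 32 with no filter, 6 of 20 with a mean count of at least 5, and 0 with an estimated correlation and with fry, and ranged from 2 to 5 when libraries or patients were left out. Adjusted p with an estimated correlation and with fry was 0.305 and 0.114 for cytotoxic granule genes, 0.305 and 0.0533 for cytoskeleton genes, and 0.864 and 0.232 for mitochondrial transcripts, whose leave-one-out range was 4.19e-05 to 0.06.

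Lists that had not passed also turned direction, without passing in the new one. T cell receptor signalling did so with a count of at least 10 in 3 libraries (adjusted p = 0.983), thinning (0.959) and fry (0.571); AP-1 genes with no filter (0.608), a mean count of 5 (0.871), limma-voom (0.977) and fry (0.573); heat shock genes with no filter (0.821), a count of 10 (0.983), a mean count of 5 (0.882), limma-voom (0.977) and fry (0.571). Glycolysis did so with no filter (0.792), a mean count of 5 (0.871) and fry (0.171), and ribosomal protein genes with library totals (0.858), edgeR (0.877) and edgeR with the replicate block (0.847). Leave-one-out ranges of adjusted p, with changes of direction, were 0.372 to 0.944 for interferon response, 0.325 to 0.997 for T cell receptor signalling, 0.607 to 0.98 for AP-1 genes, 0.578 to 0.997 for glycolysis, 0.00519 to 0.997 for the nuclear respiratory chain and 0.0248 to 0.997 for ribosomal protein genes.

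Leaving out a library or patient moved the fold change of 11 of the 54 named genes by more than 1.5 times, a limit set after the values were seen (NKG7, GZMA, KLRB1, BACH2, ITGA4, CD69, DUSP1, JUNB, PFKP, RORA and S100A9). Of the 54, 7 with small fold changes changed sign. BCL2 went to -0.0852 with edgeR, -0.0525 with edgeR and the replicate block and -0.405 after thinning, S100A8 to -0.226, -0.109 and, with DESeq2, -0.0874, CD3D to -0.0173, -0.0457, -0.0258 after thinning and -0.0913 with limma-voom, and ITGA4 to 0.16 with limma-voom. Leave-one-out ranges were -1.36 to 0.26 for BACH2, -0.996 to 0.756 for ITGA4, -0.021 to 0.503 for BCL2, -0.27 to 0.65 for S100A8, -0.86 to 0.32 for S100A9 and -0.38 to 0.33 for HBA2. The difference in ribosomal protein share ranged from -0.273 to 0.371 percentage points and that of the 20 most counted genes from -0.567 to 5.69, that of the cytotoxic share from 0.0549 to 0.142 and that of genes detected at equal depth from -1124 to -49.5. Genes detected differed by 1635 before thinning against -610 after it.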

Other observations

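The tests of other cell types, of thinned depth and of correlation, the list sums, and the estimated correlation and fry without a filter were chosen after the result was seen. With no filter on low counts, 32 lists could be tested and further lymphocyte genes came into view. The NK-type receptor list was higher in CD4 CTL, with 17 of 20 members positive and a median log2 fold change of 1.08 against 0.13 for all genes (limma and camera, adjusted p = 2.62e-06; 0.0813 with an estimated correlation; fry 0.0379). Its members CD300A, an inhibitory receptor, and KLRD1, the CD94 chain of NK receptors, had log2 fold changes of 2.84 ± 0.79 and 2.07 ± 0.67 (SE) and, chosen after their values were seen, passed adjusted over the list alone. When a library or patient was left out they ranged from 2.29 to 3.37 and from 1.17 to 2.66, KLRD1 being lowest without CD4 CTL replicate 2. Cytotoxic granule genes had 17 of 19 members positive and a median of 1.02, against 1.47 for the 9 tested in the main fit (camera, adjusted p = 1.33e-07, or 0.0813 with an estimated correlation and 0.0141 with fry). PRF1, GZMB and CTSW, chosen after their values were seen, had 1.025 ± 0.614, 0.013 ± 0.709 and -0.863 ± 0.736 (SE), and none of the 3 passed adjusted over the list alone. Effector transcription factors (14 of 16 positive, adjusted p = 0.00747), the nuclear respiratory chain (0.0043), ribosomal protein genes (0.00142) and the Th17 list (6 of 6 positive, 0.032, holding RORA, see the last paragraph) also passed, and with an estimated correlation gave adjusted p of 0.223, 0.774, 0.893 and 0.749. Respiratory chain and ribosomal protein genes had medians of 0.358 and 0.287, near the 0.32 of all genes tested in the main fit. With no filter they were compared with many genes of few reads, and the median of all genes was 0.13. These 2 calls therefore cannot be told apart from the shift shared by the genes tested in the main fit. MYC, chosen after its value was seen, had -2.72 ± 0.72 in the quiescence list (adjusted p = 0.34 for the list) and passed adjusted over that list alone, with a leave-one-out range of -3.72 to -2.03. No member of these lists passed adjusted over all genes. GPT2, the mitochondrial alanine aminotransferase, chosen after its values were seen, was past the threshold with no filter (3.78, adjusted p = 0.00875) and with the replicate block in DESeq2 (4.07, adjusted p = 0.0435), and its normalised counts were 2.64 ± 1.75 in naive CD4 and 61.5 ± 42.8 in CD4 CTL (SD, n = 3). It also passed without CD4 CTL replicate 2 (4.68, adjusted p = 0.00986) and without the replicate 2 pair (4.49, 0.00238), and its leave-one-out range was 3.10 to 4.68. In the main fit GPT2 had an adjusted p of 0.158, and limma and edgeR with the replicate block called 0 genes.

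Lists with few or no testable members were summed over all members with a row and compared by exact permutation tests, 33 in all, in which 0.1 is the smallest p and no adjusted p lay under 0.471. Inhibitory receptor genes summed to 34.7 ± 10.9 normalised counts in naive CD4 and 58.7 ± 8.45 in CD4 CTL, profibrotic cytokines to 26.7 ± 8.20 and 52.3 ± 30.8, Th1 genes to 50.7 ± 18.8 and 67.0 ± 51.9, and senescence genes to 71.6 ± 21.6 and 60.4 ± 15.3 (SD, n = 3). Regulatory T cell genes summed to 15.7 ± 2.63 and 16.8 ± 6.50 and follicular helper genes to 12.7 ± 4.52 and 17.5 ± 7.78. Several of these levels were near the background. Means per member in naive CD4 and CD4 CTL were 2.48 and 4.19 for inhibitory receptors, 2.23 and 4.35 for profibrotic cytokines and 1.96 and 2.10 for regulatory T cell genes. B cell markers had 2.005 and 1.835, and the median gene had 1.75 and 1.74. The profibrotic list held as few as 14 reads in a library. Markers of other cells summed, in naive CD4 and CD4 CTL, to the following normalised counts: NK cell 37.4 ± 9.31 and 33.9 ± 8.88, CD8 and gamma-delta T cell 7.66 ± 5.86 and 10.4 ± 1.04, B cell 22.1 ± 8.09 and 20.2 ± 7.60, monocyte 57.2 ± 10.1 and 63.0 ± 11.3, platelet and erythrocyte 41.2 ± 15.4 and 40.8 ± 10.4.

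The higher cytotoxic granule genes in CD4 CTL were weighed against depth, other cells and chance. The number of reads alone was argued against: after thinning to equal totals the list's median lay 1.19 above all genes (mean of 10 thinnings, SE over members 0.23), against 1.15 before. This SE treats the members as independent and does not cover the spread between libraries. Thinning keeps each gene's expected share, so input amount or library quality that go with depth were not tested. NK or CD8 T cells in the sort may contribute and cannot be told apart here, although the gate requires CD3 and CD4, which should leave out NK cells, and excludes CD8: the sum of 18 markers, 10 of them also in other lists, had a ratio of 0.985 between CD4 CTL and naive CD4 against 2.5 for the cytotoxic list, but the markers averaged 2.48 normalised counts, close to the 1.92 of B cell markers, and the most abundant, SPON2, had 8.6 ± 7.9 in naive CD4 and 4.92 ± 3.39 in CD4 CTL. In the 10 splits of the 6 libraries, 2 gave a -log10 p as high as the real split (4.9), the real one included. The highest other, 11.9, came from the real grouping with the libraries of replicate 1 exchanged, which also parted all 3 pairs. Replicates 2 and 3 kept their real groups there, so that value does not show what chance gives. All splits other than the real one mix the groups unevenly and can carry part of the real difference. With 10 splits no share under 0.05 is possible. The population named by the sort remains open as a biological explanation.

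The higher mitochondrial transcripts in CD4 CTL were weighed against depth, a factor shared by all members within a library and chance. A shared factor, such as RNA quality or the state of the cells after thawing, stays open: the members' estimated correlation within groups was 0.897, but genes transcribed together correlate under any cause, so this cannot favour one. Mitochondrial rRNA, at 10.29% of reads in naive CD4 and 13.03% in CD4 CTL, was higher in only 2 of 3 patients. Depth was not tested sharply: thinning keeps each gene's expected share, and these genes together had 846 to 7886 reads in a library. Their fold changes could therefore hardly move, and input amount or library quality that go with depth stay open. The median lay 0.426 above all genes after thinning (SE over members 0.066) against 0.44 before. This SE treats the members as independent, which their correlation goes against, and does not cover the spread between libraries. As many as 3 of the 10 splits reached the real -log10 p of 3.62, the highest other being 6.2, and among the 4 splits that part all 3 pairs the highest other was 1.16. Splits other than the real one mix the groups unevenly and can carry part of the real difference. A difference in mitochondrial content between the populations was not tested. For the cytoskeleton list 1 of 10 splits, the real one, reached 5.89, the highest other being 2.14, and for the count of genes changed 1 of 10 reached 1, the highest other being 0; these splits are too few for a share under 0.05.

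Genes not known as abundant T cell transcripts led the counts in all 6 libraries. ACADSB, a mitochondrial acyl-CoA dehydrogenase (chromosome 10, 123008979 to 123058311), took 14.3% of reads on average, followed among nuclear genes by MTRNR2L8, a near copy of mitochondrial rRNA (3.22%), PNMA8C (2.47%), PDZD4 (1.84%), SLC22A13 (1.28%), MTRNR2L12, another near copy (1.16%), and RORA (1.12%), and GAPDH had 6 reads in naive CD4 and 26 in CD4 CTL in all, all chosen after their values were seen. Priming at A-rich stretches is a possible explanation that stayed open: of the 30 leading nuclear protein-coding genes other than ribosomal protein, MTRNR2L and HLA genes, 14 had a 20-base window with at least 16 A in an annotated transcript, against a median of 12 in 10000 length-matched random sets (97.5th percentile 17), and introns were not searched. These sets, used below too, came from other protein-coding genes with a mean normalised count of at least 5, which such priming may also reach. The 14 took 4.46% of reads and the other 16 took 22.4%, and ACADSB, PNMA8C, PDZD4 and SLC22A13 had no such window. Sequence shared with abundant noncoding RNA stayed open too, with 17 of the same 30 genes, MTRNR2L genes left out, sharing a 30-base stretch with mitochondrial, 5S or 5.8S rRNA or 7SL RNA, which resembles Alu repeats, against a median of 13 (97.5th percentile 18). The 7SL sequences were chosen by gene name, which did not leave out pseudogene copies. A shared stretch may therefore match a copy that is not abundant. The 17 took 21.8% of reads, with ACADSB among them, and the other 13 took 5.11%. These sums of reads were chosen after the values were seen and not compared with random sets. No biological explanation was tested.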
